A study of Homo sapiens with 6 samples.

How the data were processed

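RNA was extracted from H1299 cells treated for 24 h with DMSO or RSL3, with 3 libraries per group, and messenger RNA was enriched on oligo(dT) beads, per the labels' protocols. Whether the library kit kept the strand is not given in the sources used here, so reads of overlapping or antisense genes were not told apart. Samples were grouped by their treatment label, and replicate numbers came from the sample titles.

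The deposited table held, per gene and library, expected counts and FPKM values computed by the authors. Bowtie2, RSEM 1.3.1 and the genome GRCh38.p13 are named, without their roles, per the submitters' processing notes. The authors' deposited table also gave a log2 fold change, a p-value and a q-value per gene, with DESeq2 named for the p-values and q-values per the file headers and version 1.4.5 given in the processing notes. Expected counts, as RSEM gives them, are model estimates that divide reads shared by similar transcripts. Only 23.0% of them were whole numbers, judged at the 2 decimals of the file, and they were rounded to whole counts before testing. Near-identical copies can take reads from each other in such estimates, which affects HSPA1A and HSPA1B, EIF3C and EIF3CL, PLGLB1 and PLGLB2, and U2AF1 and U2AF1L5. The table held 18090 coding genes, all named by a symbol and a gene number, and 20 lines that carried on a preceding annotation were left out. Of the gene numbers, 18022 matched the reference gene table (assembly GRCh38.p14), 17752 of them under the same symbol. Older symbols of list members were matched through that table. Genes of the mitochondrial genome and noncoding genes were not analysed here. Positions are those of the deposited table.

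Totals lay between 18323728 and 18550969 counts per library, and 3466 genes with low counts were not tested. Counts between libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom from 1.53 to 1.78 between DMSO libraries and from 2.09 to 4.72 between RSL3 libraries, against 20.95 to 33.42 between groups. No library was therefore counted as a second reading of another, though this cannot tell separate cultures from separate libraries of 1 culture. The division of reads between similar transcripts can itself add spread to expected counts. EIF3CL, for example, held 103, 246 and 211 counts in the DMSO libraries. The values from 1.53 to 1.78 therefore cannot exclude repeated readings.

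Genes were filtered with filterByExpr (minimum count 10, minimum total count 15) and scaled by TMM. The quasi-likelihood F test of edgeR 4.0.16 compared RSL3 with DMSO with treatment as the only term, leaving 4 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all 14624 genes tested. Genes were called at an adjusted p under 0.05. The common biological coefficient of variation was 3.35%. Standard errors are the absolute log2 fold change divided by the square root of the F statistic, and means and SDs are of TMM-scaled CPM. Before the data were examined, 31 gene lists with 768 memberships, the design, most alternatives and the rule for named genes were fixed. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 30 lists that could be tested, and counts were also taken with p-values adjusted over the list alone. The list of mitochondrially encoded messages had no member in the table and was not tested, and 19 memberships in all had no row. R 4.3.3 was used, with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 for reading and plotting.

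The named genes are GPX4, SLC7A11, ACSL4, AIFM2, CHAC1, PTGS2, HMOX1, TFRC and RGS4, whatever their values. To these were added the 6 genes that rose and the 6 that fell most among called genes with separated groups and a mean of at least 5 CPM in a group. Each called list gave the 3 members with the smallest adjusted p, and each list not called gave up to 2. A few genes that this rule selects, and 1 called list, are not reported here. CCN2, ANKRD1, PTPRC, COL1A1 and the proteasome genes fall outside this rule and were chosen after their values were seen.

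The script was tested on simulated counts drawn from the real means and library sizes, with 50 genes changed at each of 4 fold sizes among 14474 tested genes. For RSL3 against DMSO it recovered 48% of genes changed 1.2-fold, 86% at 1.5-fold, 94% at 2-fold and 100% at 4-fold, with 13 false calls. Far fewer genes were changed there than the 5082 (34.8%) called in the real data. The adjusted threshold depends on that share, so these rates and the number of false calls need not carry over. A list of 25 genes shifted 1.5-fold was called, and 0 of 99 unshifted lists were. The simulated genes were drawn independently of each other, so false calls among lists of correlated genes were not tested. In the real lists the estimated correlation between genes reached 0.594, for the metallothioneins. The alternatives were DESeq2 size factors, library totals alone, no filter or a filter of 1 CPM in 3 libraries, the replicate number as a block, leaving out each library, the Wald test of DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM, a test against a 2-fold change, an adjusted p under 0.01, camera with an estimated correlation, and the rotation test fry. GC content and length of the longest coding transcript per gene came from GENCODE release 29, with 14492 of the tested genes (99.1%) matched, and their trends were fitted with mgcv 1.9.3.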

Results

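The transcriptome of H1299 cells, an established human lung cancer line, was measured by RNA sequencing after 24 h with RSL3 or with its solvent DMSO. RSL3 is a small molecule known to inactivate GPX4, the selenoenzyme that reduces lipid hydroperoxides, and to trigger ferroptosis, an iron-dependent form of cell death. Each group held 3 libraries. The stated purpose was to describe molecules connected with ferroptosis, and the design implies 1 comparison, RSL3 against DMSO. The depth was close to even. The DMSO libraries held 18550969, 18497046 and 18512664 expected counts over 18090 coding genes, and the RSL3 libraries held 18410280, 18410694 and 18323728. EEF1A1 was the most abundant gene in every library, with between 1.15% and 1.26% of the counts. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

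RSL3 raised a small set of genes strongly and moved many others slightly. CCN1, which encodes a secreted matrix protein, rose most, from 114.7 ± 12.5 CPM with DMSO to 7970 ± 479 CPM with RSL3 (mean ± SD, n = 3 each). The oxidative stress genes HMOX1 and OSGIN1 followed, at log2 fold changes of 4.90 ± 0.11 and 4.27 ± 0.11 (estimate ± SE). Among the genes that fell, HILPDA, a lipid droplet protein, dropped from 132.4 ± 4.73 to 50.7 ± 2.66 CPM, the chemokine receptor CXCR4 from 13.6 ± 0.294 to 5.39 ± 0.511 CPM and the homeobox gene HOXA13 from 111.6 ± 1.96 to 47.8 ± 1.94 CPM. Of 14624 genes tested with edgeR's quasi-likelihood test, 5082 (34.8%) passed a Benjamini-Hochberg adjusted p of 0.05, 2654 of them higher and 2428 lower with RSL3. This balance depends on the setting, since lower genes outnumbered higher ones when libraries were scaled by their totals alone (2294 higher, 2936 lower). Most of these changes were small. The fold change was under 1.5 for 4534 of the called genes (89.2%), and only 155 had an estimate of at least 2-fold, 143 higher and 12 lower. The 3 RSL3 libraries lay wholly above or below the 3 DMSO libraries for 6895 genes (47.1%), where chance alone gives 10%. The 2-fold count rests on point estimates, since 36 genes passed a test against a 2-fold change itself. The number at least 2-fold lower also moved with single libraries, to 23 without RSL3 replicate 2 and to 27 without RSL3 replicate 3.

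**Figure D1:**
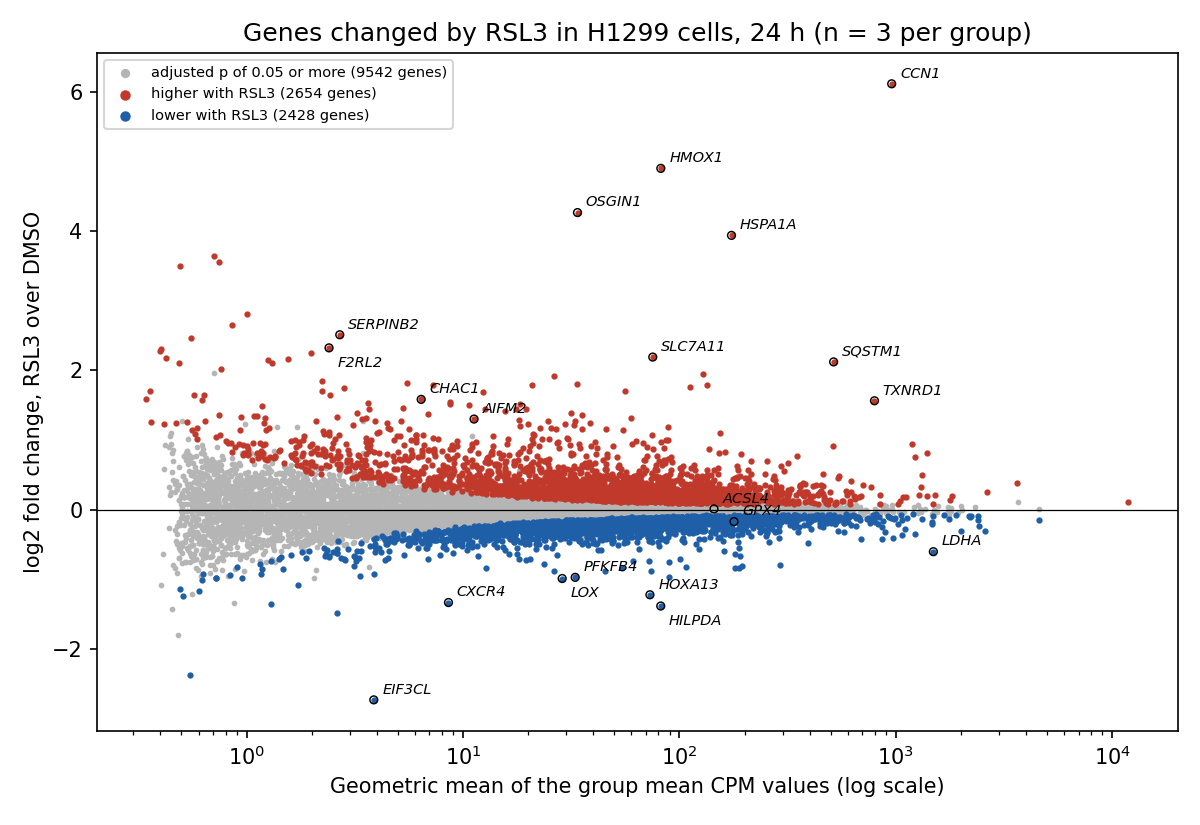
Log2 fold change of each tested gene, RSL3 over DMSO, against the geometric mean of its group mean CPM on a log axis, with each point 1 of 14624 genes. The 2654 genes higher with RSL3 are red, the 2428 lower are blue, and CCN1 lies alone at the top at a log2 fold change of 6.12.

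CCN1 (chromosome 1, 85580761 to 85583950, GRCh38.p13) showed a log2 fold change of 6.12 ± 0.07 (edgeR adjusted p = 2.49e-17). It reached 8083, 7444 and 8381 CPM in the RSL3 libraries, against 125.1, 118.2 and 100.8 CPM with DMSO. HMOX1 (chromosome 22, 35381096 to 35394207), which encodes the heme-degrading enzyme heme oxygenase-1, stood at 444.6, 520.8 and 381.0 CPM with RSL3 and at 15.04, 15.13 and 14.8 CPM with DMSO (edgeR adjusted p = 2.46e-13). OSGIN1, an oxidative stress response gene, rose from 7.70 ± 0.812 to 148.5 ± 20.5 CPM (edgeR adjusted p = 1.23e-12). SERPINB2, a serpin that inhibits urokinase, and F2RL2, a protease-activated receptor gene, rose at low levels, from 1.13 to 6.46 and from 1.07 to 5.40 CPM (edgeR adjusted p = 8.81e-08 and 6.16e-07). HSPA1A, an inducible HSP70 gene, rose by a log2 fold change of 3.94, but it shares reads with its near-identical copy HSPA1B. The summed counts of HSPA1A and HSPA1B rose from 1746 ± 35.8 to 2622 ± 115 CPM, 1.50-fold, so the larger value for HSPA1A alone is uncertain. The largest fall by estimate, EIF3CL at -2.73, is also uncertain. EIF3CL is a near-identical copy of EIF3C, and their summed counts stood at 733.7 ± 7.35 and 725.6 ± 5.27 CPM, a log2 ratio of -0.02 (edgeR adjusted p = 0.649 for the sum). HILPDA, CXCR4 and HOXA13 showed log2 fold changes of -1.38 ± 0.04, -1.33 ± 0.10 and -1.22 ± 0.04 (edgeR adjusted p = 3.14e-11, 2.21e-07 and 4.86e-11). LOX, which encodes the collagen-crosslinking enzyme lysyl oxidase, and PFKFB4, a regulator of glycolytic flux, fell by 0.99 and 0.97 on the log2 scale (edgeR adjusted p = 8.13e-08 and 2.09e-08).

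**Figure D2:**
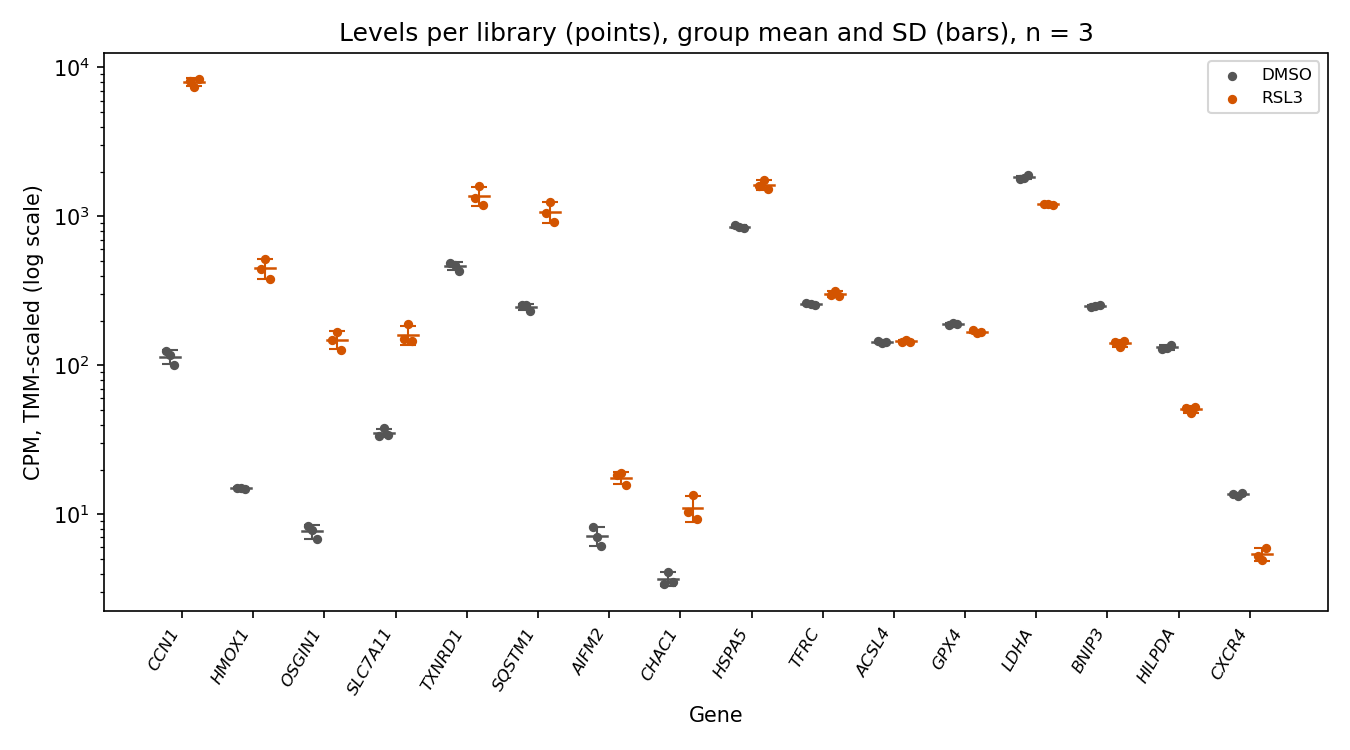
Scaled CPM per library on a log axis for 16 named genes, DMSO in grey and RSL3 in orange, with points for the 3 libraries of each group and bars for the mean and SD. HMOX1 stands at 14.8 to 15.13 CPM with DMSO and at 381.0 to 520.8 CPM with RSL3, while the ACSL4 libraries of both groups overlap.

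Genes of ferroptosis itself moved both ways, with SLC7A11, SLC3A2, TXNRD1 and AIFM2 higher and GPX4 slightly lower. SLC7A11 (chromosome 4, 138164097 to 138243126), the cystine transporter subunit that feeds glutathione synthesis, rose from 35.2 ± 2.35 to 161.0 ± 24.0 CPM, a log2 fold change of 2.19 ± 0.09 (edgeR adjusted p = 3.34e-10). SLC3A2, its partner chain, rose by 1.10 and TXNRD1, the cytosolic thioredoxin reductase, by 1.56 on the log2 scale (edgeR adjusted p = 1.06e-09 and 2.32e-09). AIFM2, which encodes the ubiquinone-reducing suppressor FSP1, rose from 7.16 ± 1.04 to 17.7 ± 1.65 CPM, 2.46-fold (edgeR adjusted p = 8.27e-07). GPX4 (chromosome 19, 1103994 to 1106779) fell from 189.5 ± 3.60 to 168.4 ± 3.47 CPM, by 0.17 ± 0.03 on the log2 scale (edgeR adjusted p = 0.00069). Of 25 ferroptosis suppressors, 8 rose, 5 fell and 12 did not pass (camera adjusted p = 5.56e-07, higher). The same counts of 8 and 5 were found when adjusted over the list alone, and the list gave an adjusted p = 0.0998 with an estimated correlation. Its median log2 fold change was 0.05, with 5 members at least 2-fold higher. Of 29 tested ferroptosis drivers, 7 rose and 8 fell, or 8 and 8 adjusted over the list alone, and the list was not called (camera adjusted p = 0.714). KEAP1, the adaptor that marks NRF2 for degradation, and the lipid phosphatase gene LPIN1 rose by 0.47 and 0.48 on the log2 scale (edgeR adjusted p = 1.2e-05 and 1.25e-05). ACSL4, which loads polyunsaturated fatty acids into lipids, stood at 143.8 ± 2.36 and 145.0 ± 3.37 CPM (log2 fold change 0.01 ± 0.03, edgeR adjusted p = 0.820). TFRC, the transferrin receptor, rose by 0.22 ± 0.03 on the log2 scale (edgeR adjusted p = 0.00025). CHAC1 and PTGS2, often used as transcript markers of ferroptosis, rose from 3.70 ± 0.379 to 11.1 ± 2.21 CPM and from 0.321 ± 0.0924 to 1.02 ± 0.121 CPM (edgeR adjusted p = 2.9e-06 and 0.00218). PTGS2 rests on 5 to 8 counts per DMSO library and 17 to 21 per RSL3 library. RGS4, another such marker, held between 6 and 12 counts per library and was not tested.

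Targets of NRF2, the transcription factor of the antioxidant response, included HMOX1 and OSGIN1, whose log2 fold changes were the largest after that of CCN1. Of 29 tested members, 17 rose, 3 fell and 9 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of 0.44. The list was called higher (camera adjusted p = 7.54e-41), with an adjusted p = 0.0582 with an estimated correlation. HMOX1, OSGIN1 and SLC7A11 led it. Iron handling genes moved both ways, with 9 of 22 higher and 4 lower under either adjustment (camera adjusted p = 5.55e-07; adjusted p = 0.148 with an estimated correlation). FTH1, the ferritin heavy chain, rose from 463.0 ± 6.88 to 644.9 ± 23.4 CPM and the metal importer gene SLC39A14 from 122.7 ± 4.96 to 185.1 ± 9.79 CPM (edgeR adjusted p = 3.16e-08 and 1.19e-07). HMOX1 also belongs to this list, and the mean log2 fold change of 0.33 lay far above the median of 0.02. Of 5 tested metallothionein genes and their regulators, 3 rose and none fell under either adjustment: MT2A by 1.32, the zinc exporter gene SLC30A1 by 0.59 and MT1X by 0.85 on the log2 scale (camera adjusted p = 9.61e-05; adjusted p = 0.183 with an estimated correlation). Metallothionein transcripts are similar in sequence, so reads may be divided among them. Glutathione metabolism was divided, with 7 of 24 genes higher and 6 lower, or 8 and 6 adjusted over the list alone (camera adjusted p = 0.0874, not called). GCLM and GCLC, the subunits of the rate-limiting enzyme of glutathione synthesis, rose by 1.95 and 0.87 on the log2 scale (edgeR adjusted p = 3.34e-10 and 6.27e-08). The glutathione list passed without RSL3 replicate 2 (camera adjusted p = 0.00609) or RSL3 replicate 3 (camera adjusted p = 0.0198). Its median of -0.02 and mean of 0.21 differ in sign. Of 26 selenoprotein genes, 6 rose and 8 fell under either adjustment (camera adjusted p = 0.714). TXNRD1 and SELENOS, an endoplasmic reticulum membrane selenoprotein, were the first by adjusted p, at log2 fold changes of 1.56 and 0.67. That list's median of -0.01 and mean of 0.06 also differ in sign. SLC7A11, FTH1 and TXNRD1 each belong to 3 of the lists, and 24 of the 657 genes in the tested lists belong to more than 1.

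Genes of protein folding stress rose together. Of 20 endoplasmic reticulum chaperones and their regulators, 17 rose and 1 fell under either adjustment, at a median log2 fold change of 0.48 (camera adjusted p = 9.7e-33; adjusted p = 0.0189 with an estimated correlation). HSPA5, the chaperone BiP, rose from 853.7 ± 17.4 to 1634 ± 121 CPM, and HERPUD1 and PDIA4 rose by 0.89 and 0.67 on the log2 scale (edgeR adjusted p = 7.1e-10, 1.9e-09 and 1.99e-09). Of 35 targets of ATF4 and the integrated stress response, 25 rose and 5 fell, or 26 and 5 adjusted over the list alone (camera adjusted p = 2.82e-21; adjusted p = 0.0189 with an estimated correlation). Besides SLC7A11 and SLC3A2, PPP1R15A, the eIF2α phosphatase subunit GADD34, led this list, rising from 37.1 ± 0.857 to 81.7 ± 4.88 CPM (edgeR adjusted p = 9.25e-10). Of 21 cytosolic heat shock genes, 18 rose and none fell under either adjustment, with a median log2 fold change of 0.25 (camera adjusted p = 4.22e-25; adjusted p = 0.0998 with an estimated correlation). Besides HSPA1A, whose value is uncertain, DNAJB1 and the constitutive HSC70 gene HSPA8 rose by 0.87 and 0.82 on the log2 scale (edgeR adjusted p = 1.78e-08 and 2.06e-08). Autophagy and lysosome genes of the fixed list rose in 16 of 30 cases and fell in 1 under either adjustment (camera adjusted p = 5.55e-07; adjusted p = 0.148 with an estimated correlation). Broader sets of the deposited annotation were divided. Lysosome genes rose in 31 of 121 cases and fell in 25 (camera adjusted p = 0.804). The larger autophagy set rose in 47 of 137 cases and fell in 24 (camera adjusted p = 0.326). A smaller autophagy set of 31 genes was called higher (camera adjusted p = 0.0173; adjusted p = 0.535 with an estimated correlation). SQSTM1, the selective autophagy receptor p62, rose from 247.0 ± 12.5 to 1076 ± 167 CPM, a log2 fold change of 2.12 (edgeR adjusted p = 2.22e-10). GABARAPL1 and MAP1LC3B, which encode autophagosome membrane proteins, rose by 0.66 and 0.52 on the log2 scale (edgeR adjusted p = 3.73e-08 and 1.98e-07).

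Targets of HIF and enzymes of glycolysis fell, and theirs was the only list of 30 that camera with the preset correlation called lower. Of 29 members tested, 24 fell and none rose, at a median log2 fold change of -0.40, and adjusted over the list alone 24 fell and 1 rose (camera adjusted p = 6.99e-42; adjusted p = 0.00924 with an estimated correlation). LDHA, the lactate dehydrogenase A chain, fell from 1836 ± 46.5 to 1208 ± 12.4 CPM (edgeR adjusted p = 4.93e-10). PDK1, which holds pyruvate back from mitochondrial oxidation, fell from 142.3 ± 3.83 to 80.5 ± 0.413 CPM and the mitophagy receptor gene BNIP3 from 250.9 ± 5.27 to 140.7 ± 7.36 CPM (edgeR adjusted p = 5.58e-10 and 9.46e-10). The glycolytic enzymes alone gave 13 lower of 15, at a median of -0.37, and the other members 11 lower of 14, at a median of -0.60. PFKFB4, among the genes with the largest falls, is a member of this list. LOX and HILPDA, also among those genes, are known HIF targets outside it. They were picked by the size of their falls, so they are no separate test of HIF targets. Broader hypoxia sets, given further below, were not called (camera adjusted p = 0.0974 for hallmark hypoxia and 0.109 for HIF-1 signaling).

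Inflammatory and immediate early genes rose at mostly low to moderate levels. Of 19 tested NF-κB targets and cytokines, 16 rose and none fell, or 17 and 1 adjusted over the list alone, with 9 at least 2-fold higher (camera adjusted p = 1.99e-16; adjusted p = 0.128 with an estimated correlation). TRAF1, a TNF receptor adaptor, rose from 11.2 ± 0.336 to 38.8 ± 5.08 CPM, the chemokine gene CXCL2 from 17.9 ± 2.27 to 62.9 ± 9.75 CPM and RELB from 6.89 ± 0.490 to 22.3 ± 5.23 CPM (edgeR adjusted p = 4.41e-09, 1.5e-08 and 1.18e-06). Interferon-stimulated genes rose in 15 of 29 cases and fell in none under either adjustment (camera adjusted p = 0.00027; adjusted p = 0.150 with an estimated correlation). OAS3, IFIH1 and SAMD9 led that list, at log2 fold changes of 0.73, 0.64 and 0.71. Of 27 immediate early genes, 17 rose and 3 fell, or 18 and 5 adjusted over the list alone (camera adjusted p = 2.89e-05; adjusted p = 0.293 with an estimated correlation). KLF6 and DUSP1 rose by 0.57 and 0.59, while JUN fell by 0.32 on the log2 scale.

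Sterol genes of the fixed list rose modestly on balance. Of the deposited annotation's sets, hallmark cholesterol homeostasis was called higher, with 32 of 72 genes higher and 14 lower (camera adjusted p = 0.0127; adjusted p = 0.215 with an estimated correlation). Its steroid biosynthesis pathway was not called, with 6 of 19 higher and 4 lower (camera adjusted p = 0.755). Of 25 genes of cholesterol synthesis and uptake, 15 rose and 2 fell under either adjustment, at a median log2 fold change of 0.12 (camera adjusted p = 0.000577; adjusted p = 0.128 with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose by 0.47 on the log2 scale (edgeR adjusted p = 1.18e-06). Fatty acid synthesis genes rose in 4 of 20 cases and fell in 4 (camera adjusted p = 0.501). SCD, the stearoyl-CoA desaturase, fell by 0.28 and the elongase gene ELOVL5 rose by 0.31 on the log2 scale (edgeR adjusted p = 5.13e-07 and 1.46e-05).

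Apart from CCN1, targets of the coactivators YAP and TAZ moved in both directions. Of 20 targets, 7 rose and 4 fell, or 7 and 7 adjusted over the list alone. The list was called higher (camera adjusted p = 4.36e-07; adjusted p = 0.111 with an estimated correlation), but its median log2 fold change was -0.02 and its mean 0.35. Without CCN1 the call was lost (camera adjusted p = 0.602). NT5E, an ectoenzyme that makes adenosine, and MYOF rose by 0.77 and 0.56 on the log2 scale (edgeR adjusted p = 8.93e-06 and 2.65e-05). CCN2 and ANKRD1, classical targets singled out after the values of the list were seen, gave log2 fold changes of -0.11 ± 0.09 and -0.24 ± 0.21 (edgeR adjusted p = 0.324 and 0.415).

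**Figure D3:**
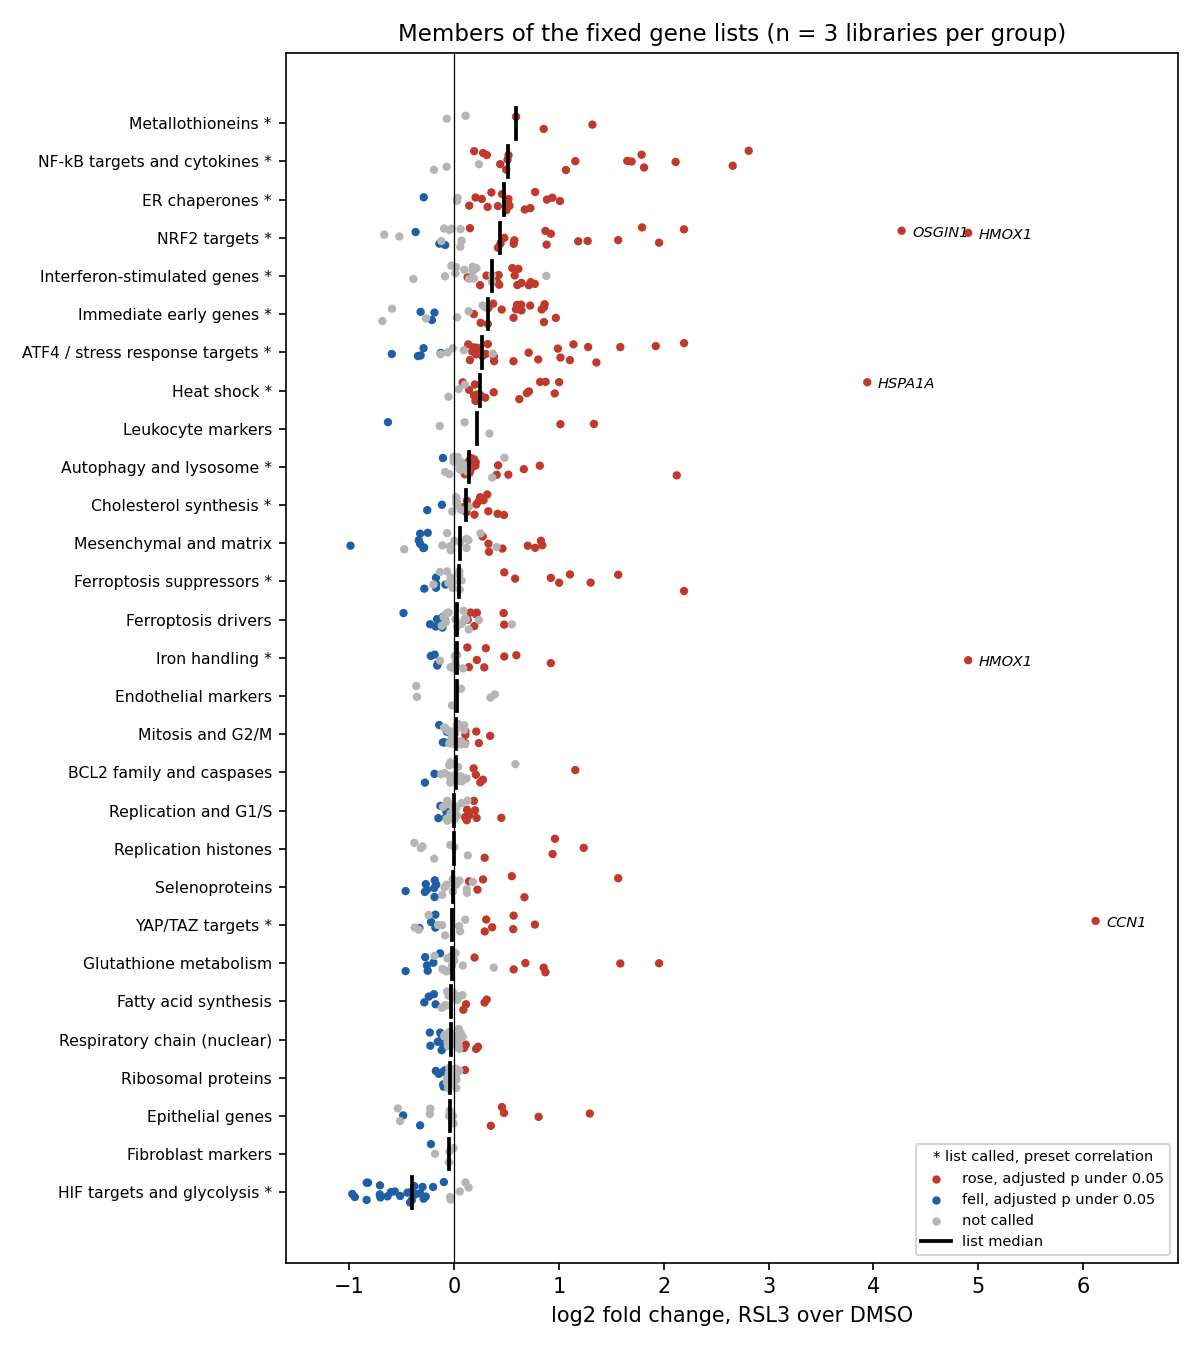
Log2 fold change, RSL3 over DMSO, of each tested member of 29 fixed gene lists, 1 point per gene, with red for genes that rose, blue for genes that fell, grey for genes not called and a black bar at the list median. The HIF and glycolysis list lies to the left, at a median of -0.40, and CCN1 lies far from the other YAP and TAZ targets.

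The following lists were not called. Genes of DNA replication and the G1/S transition rose in 9 of 30 cases and fell in 4, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.657). CCNE2 and CDC6 rose by 0.45 and 0.19 on the log2 scale. Mitotic genes rose in 6 of 30 cases and fell in 4 (camera adjusted p = 0.714), with NDC80 and HMMR up by 0.34 and 0.24. Replication-dependent histone genes, whose messages lack a poly(A) tail and are poorly captured by oligo(dT), rose in 4 of 11 cases (camera adjusted p = 0.612), led by H2BC4 and H2BC12 at 0.94 and 0.29. Nuclear-encoded respiratory chain genes rose in 4 of 36 cases and fell in 10 (camera adjusted p = 0.264), with NDUFB8 and NDUFB10 both at a log2 fold change of -0.23. Ribosomal protein genes rose in 1 of 34 cases and fell in 9 (camera adjusted p = 0.0819), with RPL27 and RPS2 at log2 fold changes of -0.18 and -0.15. That list was called lower without RSL3 replicate 1 (camera adjusted p = 0.035), without RSL3 replicate 2 (camera adjusted p = 0.0462) and when libraries were scaled by their totals alone (camera adjusted p = 0.0166). Mesenchymal and matrix genes rose in 8 of 27 cases and fell in 7, or 9 and 7 adjusted over the list alone (camera adjusted p = 0.526), with LOX lower and FN1, fibronectin, higher by 0.83. Epithelial genes rose in 5 of 15 cases and fell in 2 (camera adjusted p = 0.501), with CLDN1 and KRT18 up by 1.29 and 0.46. Genes of the BCL2 family, caspases and their inhibitors rose in 5 of 24 cases and fell in 2 (camera adjusted p = 0.501), with BIRC3 and BIRC2 up by 1.16 and 0.25. The counts adjusted over the list alone matched those over all genes for the fatty acid, mitotic, histone, respiratory chain, ribosomal, epithelial and BCL2 lists.

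Markers of leukocytes, fibroblasts and endothelial cells were tested as well, and their levels differed widely. Of 6 tested leukocyte markers, 2 rose and 1 fell under either adjustment (camera adjusted p = 0.217). CD68, which is also a lysosomal protein, rose from 16.4 ± 1.65 to 33.1 ± 5.45 CPM and the integrin gene ITGAM from 1.64 ± 0.356 to 4.15 ± 0.959 CPM (edgeR adjusted p = 7.37e-06 and 0.000346). PTPRC, the common leukocyte antigen CD45, stood at 0.768 and 0.824 CPM (edgeR adjusted p = 0.864). Of 5 fibroblast markers, 1 fell and none rose (camera adjusted p = 0.501). FBLN1 went from 80.5 ± 1.53 to 69.0 ± 3.65 CPM (edgeR adjusted p = 0.00133), COL1A1 stood at 27.2 and 26.3 CPM, and COL3A1 at 2.55 and 2.25 CPM. None of 6 endothelial markers was called by edgeR (camera adjusted p = 0.979), with KDR at 0.733 and 0.933 CPM and ERG at 0.572 and 0.751 CPM.

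In all, 15 of the 30 tested lists were called, 14 higher and 1 lower with RSL3. With an estimated correlation between genes, 3 calls held: HIF targets and glycolysis, endoplasmic reticulum chaperones, and ATF4 targets. For the lists with no member called in a direction, edgeR at an unadjusted p under 0.05 gave 1 lower NF-κB target, 2 lower histone genes and 1 higher HIF or glycolysis gene. It gave 0 lower heat shock genes, 0 lower metallothionein genes, 0 lower interferon-stimulated genes, 0 higher fibroblast markers and 0 endothelial markers in either direction, and DESeq2 called 0 in each of these 8 cases. In the authors' deposited table, 3313 genes had a q-value under 0.05, of which 1892 were higher and 1421 lower with RSL3. Of these, 3308 were among the genes tested here, and all 3308 were also called by edgeR with the same sign.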

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

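Summing pairs of near-identical genes and leaving out the most changed member of each list were chosen after seeing the data, and the other alternatives beforehand. No fixed list called by camera and no named gene of the report was called in the opposite direction, but the balance of higher and lower genes turned round in 3 alternatives. The number of called genes ranged from 3175 at an adjusted p under 0.01 (1400 lower) to 5368 without RSL3 replicate 3, and the fewest without 1 library were 3726. DESeq2 called 3546, with 1545 lower and 6 at least 2-fold lower. Lower genes outnumbered higher ones with scaling by totals alone (2936 against 2294), on log2(FPKM + 1) (2539 against 2063) and on log2(FPKM + 0.1) (2522 against 2055). The count of genes at least 2-fold changed was 36 in the test against 2-fold (33 higher, 3 lower), 51 on log2(FPKM + 1) (47 higher, 4 lower) and 87 on log2(FPKM + 0.1) (81 higher, 6 lower). The FPKM alternatives changed the measure, the test and the filter together, and the causes of these shifts were not tested. Without a filter 20 genes were at least 2-fold lower, and without single libraries 12 to 27.

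Camera with an estimated correlation called 3 lists. The adjusted p then rose to 0.0998 for ferroptosis suppressors, 0.0582 for NRF2 targets, 0.0998 for heat shock, 0.128 for cholesterol synthesis, 0.148 for iron handling, 0.183 for metallothioneins, 0.128 for NF-κB targets, 0.15 for interferon-stimulated genes, 0.293 for immediate early genes, 0.148 for autophagy and 0.111 for YAP and TAZ targets. Fry, which asks only whether a list's genes move on balance, called 23. It added fatty acid synthesis (0.0154), glutathione metabolism (0.0154), selenoproteins (0.018), G1/S genes (0.0415), ribosomal proteins (0.0204), epithelial genes (0.00316), the BCL2 family (0.0437) and leukocyte markers (0.00668). Ribosomal proteins passed under library totals (0.0166) and ranged from 0.035 to 0.231 without single libraries, and glutathione metabolism from 0.00609 to 0.133. Without their most changed members 14 lists were called, the YAP and TAZ list being lost (0.602).

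No pairing of the libraries by replicate number was seen, which does not exclude a shared day or batch. Deviations of same-numbered libraries from their group means correlated across genes at -0.053, 0.003 and 0.047, and not every library correlated best with its own number. With the replicate block 5227 genes were called, 158 of them at least 2-fold changed, and 16 lists, glutathione metabolism among them (0.0118). Among the named genes of the report, EIF3CL alone changed sides under an alternative: it was not called when summed with EIF3C. Depth limits the low genes. PTGS2 and RGS4 lie near the lower limit of what these libraries resolve.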

Other observations

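The tests on CCN2, on fibroblast and endothelial markers, on scaling of the HIF list and on GC content between RSL3 libraries were chosen after their results had been seen, as was the look at sets of the deposited annotation. The bounds of the marker test and of the GC test between RSL3 libraries were rewritten after a first version left both undecided, and a test of depth between these libraries was set aside after it was run, because its resampling added noise of its own and their totals were nearly even. The other tests were fixed before.

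Proteasome genes rose with RSL3. Of the 43 tested genes that the deposited annotation places in the proteasome pathway, 29 rose and 0 fell by edgeR, at a median log2 fold change of 0.16 (camera adjusted p = 4.66e-10 over 341 pathways of at least 10 tested members; adjusted p = 0.630 with an estimated correlation). The base subunit gene PSMC4 rose from 84.8 ± 1.97 to 121.3 ± 9.63 CPM, and PSMB1, ADRM1 and PSMD12 rose by 0.44, 0.48 and 0.32 on the log2 scale. At an unadjusted p under 0.05 edgeR gave 32 higher and 0 lower, and DESeq2 called 29 higher and 0 lower. The annotation's ferroptosis pathway had the smallest camera p of the 341, with 16 of 38 genes higher and 4 lower at a median log2 fold change of 0.13 (camera adjusted p = 1.09e-13; adjusted p = 0.483 with an estimated correlation). In the annotation's pathway of protein processing in the endoplasmic reticulum, 75 of 163 genes rose and 16 fell (camera adjusted p = 6.37e-12; adjusted p = 0.483 with an estimated correlation). Genes of carbon metabolism fell in 43 of 98 cases and rose in 9 (camera adjusted p = 1.59e-05; adjusted p = 0.336 with an estimated correlation). Genes that the annotation places in amino acid biosynthesis fell in 27 of 62 cases and rose in 9 (camera adjusted p = 0.000362; adjusted p = 0.483 with an estimated correlation). Pathways of the annotation can share members. The overlap of these metabolic sets with each other and with the glycolytic enzymes that fell was not examined. Their falls may therefore not be separate observations. None of these sets kept its call with an estimated correlation.

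CCN1 gained 7855 CPM while other YAP and TAZ targets stayed behind, a pattern that may reflect regulation particular to CCN1. Reads reassigned from another gene of the table are argued against, since the largest loss by a single gene was 628 CPM, in LDHA. A general rise of YAP and TAZ targets is argued against by CCN2, whose 95% interval ran from -0.35 to 0.12 on the log2 scale, and 6 of the other 19 targets rose, none by more than 0.77. Fibroblasts or endothelial cells are argued against by 11 of their markers, none of them called higher. Their summed level went from 117.5 to 104.8 CPM, a change of -12.6 CPM. That sum rests mostly on FBLN1 (80.5 to 69.0 CPM) and COL1A1 (27.2 to 26.3 CPM), which the DMSO cultures also expressed, and the other markers stayed low in both groups. Faster transcription, slower decay and reads from genes outside the table stay open, and none of them was tested.

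HIF targets and glycolysis genes fell together. Their median log2 fold change was -0.43 when libraries were scaled by their totals alone and -0.40 with DESeq2 size factors. The median of all genes was -0.01 with TMM and -0.03 with totals alone, so the choice of scaling mattered little beside the fall. Such scaling moves all genes of a library alike, so the gap between the list and other genes could not change. That gap is therefore no test of normalization. After smooth trends in GC content and transcript length were removed over all genes, the median of all 29 members was -0.45, which argues against those as the whole cause. Broader sets of the deposited annotation were divided. Glycolysis and gluconeogenesis genes fell in 21 of 49 cases and rose in 2 (camera adjusted p = 7.55e-10; adjusted p = 0.336 with an estimated correlation), and 69 of 186 hallmark glycolysis genes fell and 41 rose (camera adjusted p = 0.000318; adjusted p = 0.116 with an estimated correlation). The hypoxia sets were not called: 64 of 179 hallmark hypoxia genes fell and 49 rose (camera adjusted p = 0.0974 over 50 sets), and in the HIF-1 signaling pathway 32 of 93 fell and 19 rose (camera adjusted p = 0.109). An effect of RSL3 on the genes of the fixed list is a hypothesis from the same data, and differences in cell density or oxygen between cultures were not tested.

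The RSL3 libraries differed more from each other than the DMSO libraries did. Whether they differed along the response was not settled. Over 548 called genes changed at least 1.5-fold, the median share of the mean change was 0.959, 1.15 and 0.819 in RSL3 replicates 1, 2 and 3. The mean change includes the library itself, and the genes were called from the same libraries. A high share in 1 library thus lowers the others, and the shares only describe the order. A candidate explanation is a different strength of 1 response between cultures. Across 14624 genes, which are not independent replicates, RSL3 replicate 2 minus replicate 3 correlated with RSL3 replicate 1 minus the DMSO mean at r = 0.25, between the bounds of 0.1 and 0.3 set beforehand for this Pearson correlation, so it cannot be told apart from other sources, while DMSO pairs gave 0.007 to 0.053. The Spearman correlation of the same values, for which no bound was set, was 0.401. CCN1 did not follow this order, at 8083, 7444 and 8381 CPM in RSL3 replicates 1, 2 and 3. Removing GC and length trends left r at 0.27, against 0.273 before over the same genes, which argues against these as the whole cause.

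With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 5082 called genes and 155 at least 2-fold changed, and the highest other split gave 0 and 0 by edgeR. At an unadjusted p under 0.05 the real split gave 6360 genes and the highest other split 502, and DESeq2 called at most 1 gene in another split. For the gene lists the real split called 15 and the highest other split 12. In each case no split other than the real one reached the real value. Every other split mixed DMSO and RSL3 libraries in both groups, so the treatment itself widened the spread within groups. Their counts are therefore not what chance alone would give, and the splits decide nothing about chance.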
